A study of Homo sapiens with 3 samples.

How the data were processed

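Polyadenylated RNA of 3 libraries was sequenced on Ion PI chips, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.10, Bowtie2 2.1.0, Cufflinks 2.1.1, Cuffdiff and hg19, without giving the role or settings of each. Per the file headers, the authors deposited FPKM values with interval bounds and a status, per gene and per isoform, for 3 libraries. In both tables the libraries carry generic names, and 0 of the 3 names were found in the labels. The 12 columns of each table that belong to single libraries were therefore not used, and none was assigned to an siRNA by column order or by the level of a silenced gene. While the format of the tables was inspected, the FPKM values of a few genes, RNF111 and ESRP2 among them, were seen, and they entered no step.

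Isoform identifiers, gene symbols, loci, start sites and annotated lengths, which are the same for every library, were read from the isoform table with Python 3.11.15 and pandas 2.3.3. Genes with more than 1 isoform were counted. Loci are given as the table writes them. The reference annotation was on another build and was not used here. The comparisons of siRNA groups and the 29 gene lists were set in a plan, with the rule for named genes. Whether the plan was set before the few FPKM values mentioned above were seen is not recorded. The rule for named genes always lists RNF111, ESRP1 and ESRP2. It then takes the genes with the largest differences in each comparison, up to 4 members of each list and the largest isoform shifts. Only its first part was applied, since no comparison was made. NFATC3, MOG and the splicing targets named individually were chosen after the transcript models were seen. Every member was found for 28 of the lists. For the list of mitochondrially encoded genes, 0 of 10 members were found under the symbols searched. No test was run and no p-value is given.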

Results

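The series holds 3 RNA-sequencing libraries of OS-RC-2, an established line of clear-cell renal cell carcinoma, each from cells harvested 48 h after seeding. One library came from cells given a negative control siRNA, one from cells given siRNA against Arkadia and one from cells given siRNA against ESRP2, so each group has 1 library and no replicate. Arkadia, the product of RNF111, is a ubiquitin ligase of TGF-β signalling, and ESRP2 is an epithelial regulator of splicing. The design asks how gene expression and isoform use in these cells differ when either protein is depleted. That question is not answered here. The columns of expression values carry generic names that none of the labels use, and no library was assigned to a column by its order or by its values. No expression level, fold change or isoform share is therefore reported, and the depth of each library is unknown. What follows describes only the transcript models on which expression was quantified.

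The isoform table listed 41138 isoforms of 23284 genes, with a median annotated length of 2465 bases. Of these isoforms, 34565 were coding and 6573 non-coding by the prefix of their RefSeq identifiers. A single isoform was listed for 15368 genes, and 7916 genes had more than 1. These totals count every listed entry, among them 2055 on alternative haplotype contigs of chromosome 6. On chromosomes 1 to 22, X and Y only, 7762 genes had more than 1 isoform.

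The silenced genes were represented by simple models. RNF111 had 1 isoform of 5537 bases, in a locus on chromosome 15 from 59279864 to 59389253 of hg19 as the table writes it. ESRP2 also had 1 isoform, of 4021 bases. Per the series text, ESRP2 itself was too low for FPKM. A check of its silencing in such values would therefore be weak even with the libraries assigned. ESRP2 was placed in a locus on chromosome 16 from 68119268 to 68270136, and the 3 isoforms of NFATC3 were given the same interval. NFATC3 encodes a calcium-regulated transcription factor. The interval is shared by both genes, so it does not mark the bounds of ESRP2 alone. ESRP1, the paralogue of ESRP2, had 5 isoforms of 3533 to 3806 bases in a locus on chromosome 8 from 95653363 to 95719694.

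All 30 genes of a list of splicing targets of the ESRP proteins were present, and 27 had more than 1 isoform. Whether the isoforms of a gene differed at an exon regulated by the ESRP proteins was not examined. CTNND1, which encodes p120-catenin, had 22 isoforms of 5692 to 6350 bases from 1 annotated start site. The table listed 8 isoforms of CD44, a hyaluronan receptor with variable exons, from 2261 to 5732 bases. For FGFR2, a fibroblast growth factor receptor, 9 isoforms from 4 annotated start sites were listed. ENAH, an actin regulator, had 2 isoforms of 13109 and 13172 bases. SLK, GRHL1 and RALGPS2 were the 3 listed targets with a single isoform, so no shift in isoform share could be seen for them.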

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

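None of the planned siRNA comparisons, nor any alternative to them, was run, because no column of expression values was assigned to a library. No paired analysis was possible because each group has 1 library. The settings below were chosen after seeing the data and concern the transcript models only. Genes with more than 1 isoform numbered 7762 on chromosomes 1 to 22, X and Y, 7862 with isoforms of at least 200 bases and 7169 with coding isoforms alone, against 7916 with all isoforms. The number of listed ESRP targets with more than 1 isoform was 27 under each of these settings. The settings of chromosome and length could not change it. All isoforms of the listed targets lay on these chromosomes and were longer than 200 bases.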

Other observations

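Of the annotated isoforms, 2187 lay outside chromosomes 1 to 22, X and Y, and 2055 of them were on the 7 alternative haplotype contigs of chromosome 6. For 248 genes, isoforms were listed both on a main chromosome and elsewhere. MOG, which encodes a myelin glycoprotein, had 72 listed entries, of which 9 were on chromosome 6 itself. Whether the entries elsewhere repeated the same transcripts was not examined, so 72 is not a count of distinct isoforms. How reads shared between such entries were divided is not given in the sources used here.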
